A study of Mus musculus with 6 samples.

How the data were processed

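RNA from whole mouse testis was measured by RNA sequencing in 6 libraries, 3 WT and 3 KO for 1700052I22Rik. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a VAHTS mRNA-seq v2 kit for Illumina. Per the submitters' processing notes, HISAT2 2.0.0 and the mm10 build were used. The authors deposited whole-number read counts per Ensembl gene, 1 column per library, with gene symbol, coordinates, length and biotype, per the file header. The counting tool, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping or antisense gene pairs, and of near-identical copies such as globin, ribosomal protein and histone variant genes, can therefore not be assigned with certainty. Columns were matched to samples by the genotype and replicate number in their names, and 0 columns were left unmatched. Of the 54532 gene identifiers, 54495 were found in GENCODE M21 and 53585 (98.3%) had the same coordinates there; exon positions of the target were taken from that annotation.

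Library totals were 18117593, 17794450 and 18079011 counts for WT 1 to WT 3 and 17944982, 17635045 and 17957707 for KO 1 to KO 3. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, smallest group 3), which left 19320, and TMM factors lay between 0.992 and 1.01. The comparison of KO with WT used edgeR 4.0.16, with glmQLFit and glmQLFTest on the counts, all 6 libraries and no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 0.112. CPM values are TMM-normalised, errors are SDs over 3 libraries, and intervals of fold changes are 95% intervals from the fit's moderated standard errors. A count of 0 was given a floor of 3 counts over the group, which covers counting error only. The work ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0.

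The design, the alternatives, 21 gene lists and the rule for naming genes were fixed before the data were examined. The lists were histone-to-protamine exchange, testis histone variants, acrosome and round spermatid, elongating spermatid and flagellum, manchette and head shaping, meiotic spermatocyte, piRNA and chromatoid body, spermatogonia, Sertoli cell, Leydig cell, peritubular myoid and smooth muscle, macrophage and immune, endothelial cell, epididymis, blood, p53 and apoptosis, immediate early and heat shock, interferon response, cholesterol synthesis, mitochondrial-genome transcripts and cytosolic ribosomal proteins. Hook1 is in 2 of them. Each list was tested against the other genes with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 21 lists. Camera with the correlation estimated from the residuals, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it.

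The naming rule took 1700052I22Rik, then called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted models. With fewer than 5 in a direction, the 5 with the smallest p under the same filters were taken, which applied in both directions. From each list up to 4 members with the smallest p were taken, and Tnp1, Tnp2, Prm1 and Prm2 always. Not every gene the rule takes is reported here. Other members of the lists, the genes named near the target, Star, Cyp11a1, Cyp17a1 and the genes of the closing observations were named after their values were seen.

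The alternatives were DESeq2 size factors, upper quartile scaling or library size alone in place of TMM; no low-count filter or a mean of at least 5 CPM; DESeq2; limma-voom with and without sample weights; a further requirement of an absolute log2 fold change of at least 1; protein-coding genes together with the target; the replicate number as a block; each library left out in turn; and windows of 0.2 and 5 Mb around the target. Leaving out WT 1 and KO 2 together, and removing from each library a lowess trend on gene length (span 0.3), were added after the data were seen. All 10 splits of the 6 libraries into 3 and 3 were fitted.

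The test was tested on simulated counts for the 19320 genes with the real means and library sizes, in 5 simulations with 200 changed genes each. It recovered 41.5% of genes changed 1.5-fold, 70.1% at 2-fold and 95.8% at 4-fold, all with the right sign. These were 139, 235 and 316 calls, and in the same simulations 60 of 95600 tests of unchanged genes were also called. In 5 simulations with no changed gene it made 9 calls in all. A simulated list of 25 genes raised 1.3-fold had an adjusted p of 3.02e-16, and 0 of 20 unchanged lists were called. These counts were drawn independently for each gene, so they hold no inter-gene correlation. In the real data the estimated correlation was 0.247 for the macrophage list and 0.299 for the ribosomal list. The simulation therefore cannot show how often correlated lists are called wrongly.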

Results

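RNA from whole mouse testis was sequenced in 6 libraries, 3 from wild-type (WT) testes and 3 from testes in which the long non-coding RNA gene 1700052I22Rik had been knocked out (KO). The deposited table gives read counts for 54532 Ensembl genes, of which 32986 had a count in at least 1 library. Depth was even. The total per library ran from 17635045 counts in KO 2 to 18117593 in WT 1, and the 10 most abundant genes held 3.15% to 3.38% of the counts. After a low-count filter 19320 genes were tested, which together held over 99% of the counts of each library. Pairs of libraries from the same genotype correlated across genes with a mean r of 0.987, and pairs from different genotypes likewise with a mean r of 0.987. Every pair differed by more than sampling noise, so no library was a copy of another and all 6 were counted as separate samples. The lowest chi-square per degree of freedom was 4.07, for WT 1 and KO 2, whereas the lowest within a genotype was 4.89. The check cannot show that libraries came from separate animals. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples.

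The targeted transcript was detected in every WT library and in no KO library. 1700052I22Rik (ENSMUSG00000101912) is a lincRNA gene on the minus strand of chromosome 12, from 80923432 to 80924449 in mm10. Its single annotated transcript has 379 exonic bases, with exon 1 at 80924228 to 80924449 and exon 2 at 80923432 to 80923588, and the gene overlaps 0 other annotated genes. The WT libraries held 185, 175 and 218 of its reads, or 10.7 ± 1.18 CPM (SD, n = 3). The KO libraries held 0, 0 and 0 among 53537734 reads. A count of 0 allows up to 3 counts over the group, 0.0564 CPM, so the level in KO was at least 189-fold lower; this bound covers counting error only. The difference passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 4.89e-07). A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 allows. Which part of the gene was deleted is not given in the sources used here, and counts per gene cannot separate its exons.

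**Figure D1:**
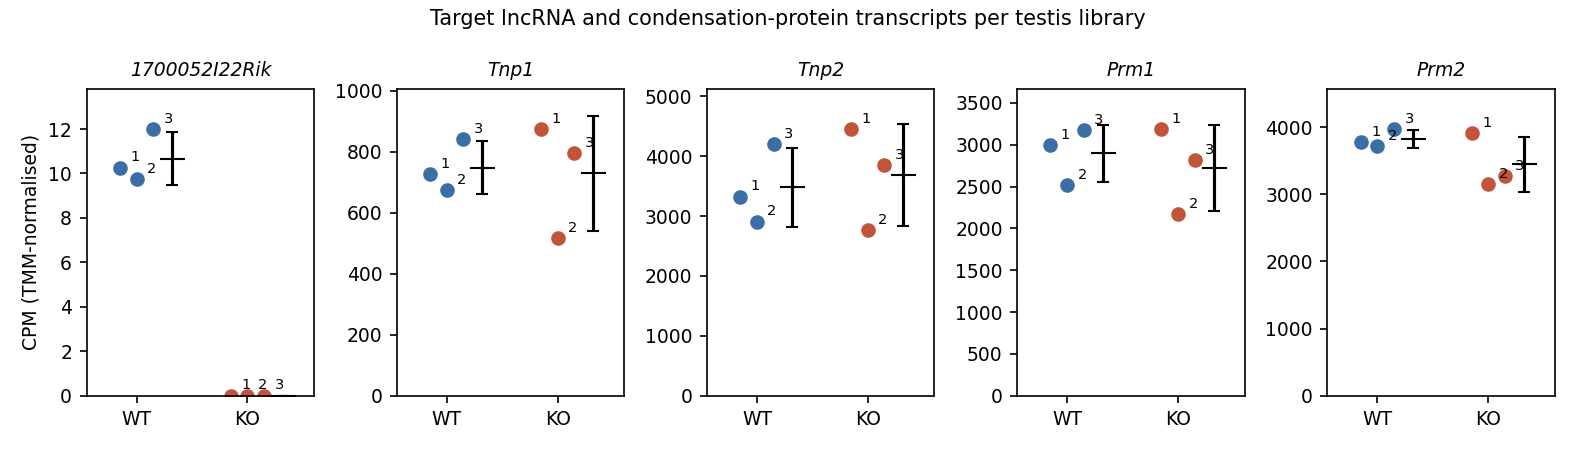
TMM-normalised CPM (y axis, linear, from 0) of 1700052I22Rik, Tnp1, Tnp2, Prm1 and Prm2 in the 3 WT and 3 KO libraries (numbered points), with the mean and SD of each genotype as a bar with caps. The target lies at 9.75 or above in each WT library and at 0 in each KO library, whereas the KO range of each of the other 4 genes overlaps the WT range.

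The comparison of KO with WT testes addressed what this transcript does in spermatogenesis, the study being about the condensation of spermatid chromatin. Apart from the target itself, no gene passed the test over all genes. The transcripts of the transition proteins and protamines, which replace histones in the condensing spermatid nucleus, were close to their WT levels. These are RNA levels, and neither protein levels nor chromatin condensation were measured in these data. Of 19320 genes, 1 was called by edgeR's quasi-likelihood test, 1700052I22Rik, with 0 higher and 1 lower. At an unadjusted p under 0.05 there were 894 genes, 466 higher and 428 lower, where 966 are expected by chance. The groups' values did not overlap for 1800 genes, 9.32% of those tested, where chance gives 10%. The next smallest adjusted p after the target was 0.182, for Rps28. Among 11040 protein-coding genes with a mean of at least 5 CPM, 10987 (99.5%) had a 95% confidence interval of the fold change that lay within 2-fold in either direction, as did 16335 (84.5%) of all tested genes. On simulated libraries of this size, each with 200 changed genes, the test found 41.5% of genes changed 1.5-fold and 70.1% of those changed 2-fold. With fewer changed genes the adjustment is stricter, so for isolated changes these shares can be lower. DESeq2 called 2 genes, adding Rps28. With no low-count filter edgeR called 50, in a fit where each gene took the spread of the trend in place of its own. Leaving out WT 2, WT 3 or KO 3 gave 3, 2 and 2 genes, and leaving out WT 1 and KO 2 together, chosen after the data were seen, gave 9.

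**Figure D2:**
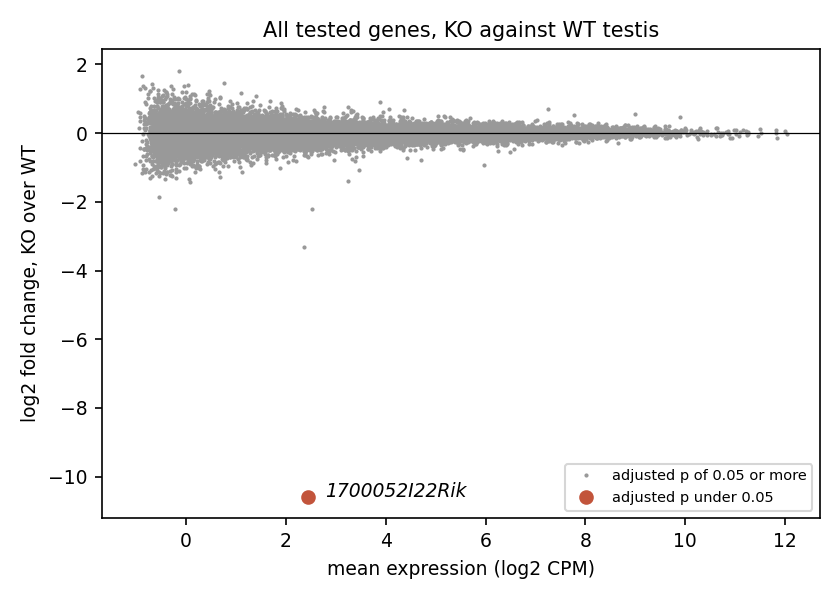
Each point is 1 of the 19320 tested genes, with mean expression in log2 CPM on the x axis and the fitted log2 fold change of KO over WT on the y axis; the red point is the gene with an adjusted p under 0.05. The called gene is 1700052I22Rik, whose plotted fold change depends on the prior count because its KO counts are 0, and the remaining genes lie around 0.

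None of the 23 tested genes of the histone-to-protamine exchange was called, either over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 in edgeR. Tnp1, encoding transition protein 1, had 748 ± 85.8 CPM in WT and 729 ± 188 in KO (SD, n = 3), a log2 fold change of -0.04 with a 95% interval of -0.34 to 0.27. Tnp2 had 3478 ± 664 and 3689 ± 855 CPM, a log2 fold change of 0.08 (95% interval -0.22 to 0.39). Prm1, encoding protamine 1, had 2895 ± 339 and 2725 ± 514 CPM (log2 fold change -0.09, 95% interval -0.33 to 0.15). Prm2 had 3824 ± 132 and 3445 ± 410 CPM (log2 fold change -0.15, 95% interval -0.31 to 0.0047), the smallest p of the list at 0.0564 in edgeR's test before adjustment. Adjusted p for these 4 genes lay between 0.965 and 0.988. Leaving out 1 library in turn moved the log2 fold change of Tnp1 from -0.19 to 0.16 and that of Tnp2 from -0.073 to 0.26. The spermatid linker histones H1fnt and Hils1 had log2 fold changes of 0.08 and 0.13, the bromodomain protein gene Brdt 0.06 and the remodeller gene Chd5 0.10. Psme4, which encodes a proteasome activator that acts in histone removal, had 0.13. The list's median log2 fold change was 0.05 (camera, adjusted p = 0.879). Of 15 tested testis histone variant and replacement histone genes 0 were called, with a median of 0.02, a mean of -0.03 and a camera direction of down (adjusted p = 0.927). Hist1h1t, Hist1h2ba and H2al1o were scarce, at 1.98, 1.53 and 1.86 CPM in WT. The 95% intervals of this list reached as far as -1.06 and 0.77, so larger changes of its scarce members could be missed. H2afx, encoding the histone variant that is phosphorylated at DNA breaks, had a log2 fold change of -0.27 and H2afv -0.25, and neither passed over the list alone (both adjusted p = 0.354).

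The named genes with the smallest p besides the target moved by modest amounts, and none passed over all genes. On the higher side were Lrrd1 (log2 fold change 0.47), Dyrk4 (0.50), which encodes a protein kinase, Nlrp5 (1.07) and Padi6 (0.71), both best known as maternal-effect genes of the oocyte, and Pnmal2 (0.36). Nlrp5 was scarce, at 1.62 ± 0.525 CPM in WT and 3.42 ± 0.160 in KO (SD, n = 3). On the lower side were Epas1 (log2 fold change -0.39), encoding a hypoxia-inducible transcription factor, Ndufa12 (-0.50), a subunit of respiratory complex I, Espn (-0.34), encoding an actin-bundling protein, and Igfbp6 (-0.50), an insulin-like growth factor binding protein. Each of these 9 genes had an adjusted p of 0.965 in edgeR's test. Rps28, encoding a protein of the small ribosomal subunit, was the exception, with 32.9 ± 2.07 CPM in WT and 19.2 ± 3.29 in KO (log2 fold change -0.78, 95% interval -1.04 to -0.51, adjusted p = 0.182). Its adjusted p was 0.000360 in DESeq2 and 0.0493 in edgeR without KO 3.

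Lists of germ cell genes showed small shifts and 0 called members. For 27 acrosome and round spermatid genes the median log2 fold change was 0.04, with 20 members above 0 (camera, adjusted p = 0.0954, 0.0218 with a mean of at least 5 CPM, 0.00300 without WT 2, 0.869 without WT 3 and 0.801 with an estimated correlation). Sun3, a nuclear envelope protein gene, had 0.27 and Izumo3 and Catsper1, an acrosomal protein and a sperm calcium channel gene, 0.18 and 0.19. For 29 genes of the elongating spermatid and flagellum the median was 0.05 (adjusted p = 0.116, 0.0467 with a mean of at least 5 CPM and 0.801 with an estimated correlation), with Hook1, needed for shaping of the sperm head, at 0.23 and Tekt5 at 0.24. The 26 manchette and head shaping genes had a median of -0.01 (adjusted p = 0.943), with Hook2 at -0.20, Clip1 at 0.15 and Kifc1 at -0.22. The 30 meiotic genes had a median of 0.00111 (adjusted p = 0.879), and the synaptonemal complex gene Syce3 and the meiotic cohesin gene Rec8 stood at -0.19 and -0.21. The 18 genes of the piRNA pathway and chromatoid body had a median of 0.04 (adjusted p = 0.499), with Piwil1 at 0.14 and Mov10l1 at -0.14. The 23 tested spermatogonial genes had a median of -0.12 (adjusted p = 0.439; median -0.00047 without WT 3), with Etv5 at -0.30, Dmrt1 at -0.26 and Gfra1 at 0.37. In each of these lists 0 members passed adjusted over the list alone.

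Markers of macrophages and other immune cells of the testis were lower in KO as a list. The 19 tested genes had a median log2 fold change of -0.31, and 17 of them lay below 0 (camera with a preset correlation, adjusted p = 5.72e-05). With an estimated correlation the adjusted p was 0.801, and 0 of the 21 lists were called. Without KO 2 the adjusted p was 0.0652 and the median -0.25. No single member passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 in edgeR. These were Lyz2, encoding lysozyme (29.8 ± 5.74 CPM in WT, 22.3 ± 4.31 in KO), the complement genes C1qa and C1qc (log2 fold changes -0.61 and -0.61) and Csf1r, the receptor for colony-stimulating factor (-0.35). Relative to the WT mean, the list median was -0.61 in KO 2, -0.21 in KO 1, -0.05 in KO 3 and -0.15 in WT 1. KO 2 and WT 1 also stood apart from the rest on the leading principal component, which held 26.6% of the variance, at -30.2 and -22.8 against 6.98 to 17.5 for the other 4.

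**Figure D3:**
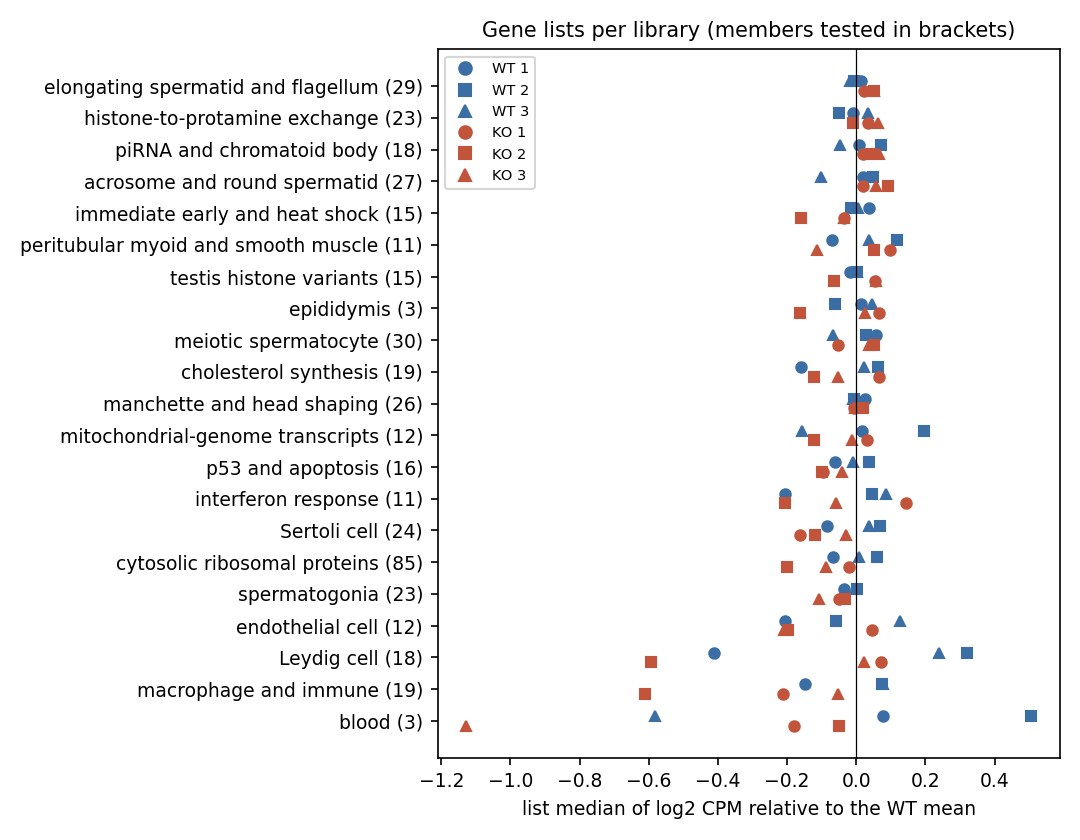
For each of the 21 gene lists, the median over its tested members of log2 CPM relative to the mean of the 3 WT libraries (x axis), with 1 symbol per library and colour for genotype. KO 2 lies lowest for the macrophage and Leydig lists, at -0.61 and -0.59, and WT 1 lies at -0.41 for the Leydig list.

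Lists of other somatic cells of the testis were not called with all 6 libraries and the low-count filter used here. For 24 Sertoli cell genes the median log2 fold change was -0.05 (camera, adjusted p = 0.0983), and the adjusted p was 0.0218 with a mean of at least 5 CPM, 0.00991 without WT 1, 0.0111 without KO 3 and 0.801 with an estimated correlation. Amhr2, the receptor for anti-Müllerian hormone, had -0.24 and Defb19, a defensin gene of Sertoli cells, -0.31. For 18 Leydig cell genes the median was -0.15 (adjusted p = 0.311), with 17 below 0. The median was -0.42 without WT 1, -0.00018 without WT 2 and -0.046 without KO 2. The list's adjusted p with the preset correlation was 5.54e-06 without WT 1 and 0.000418 without WT 1 and KO 2, but 0.982 without WT 2, 0.909 without KO 2 and 0.924 without WT 3, where the direction was up. With all 6 libraries and an estimated correlation, which was 0.659 for this list, the adjusted p was 0.964. Insl3, the Leydig cell hormone for testis descent, had 81.8 ± 2.60 CPM in WT and 42.7 ± 21.9 in KO (SD, n = 3; log2 fold change -0.94, 95% interval -1.52 to -0.35). It did not pass over all genes (adjusted p = 0.965) or adjusted over the list alone (0.0702). Insl3 was called in edgeR without WT 1 and KO 2 (adjusted p = 0.0484) and with no low-count filter (2.05e-17). The fit with no filter gave each gene the spread of the trend in place of its own. That last value therefore leaves out how far Insl3 itself varied between libraries. With 1 library left out the log2 fold change of Insl3 ranged from -1.17 to -0.56. Its level was 17.4 CPM in KO 2 and 55.6 and 55.0 in the other KO libraries. Transcripts of steroid synthesis varied within both genotypes. Cyp17a1, which makes androgen precursors, had 21.1, 358 and 243 CPM in WT 1 to WT 3 and 277, 65.1 and 145 in KO 1 to KO 3. Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, had 14.0, 183 and 125 CPM in WT and 114, 22.9 and 83.3 in KO. The 11 tested peritubular myoid and smooth muscle genes had a median of 0.02, a mean of -0.02 and a camera direction of down (adjusted p = 0.944), with Tpm2 at -0.48 and Actg2 at 0.09. The 12 endothelial genes had a median of -0.13 (adjusted p = 0.495), with Flt1 at 0.41 and Esam at -0.54.

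**Figure D4:**
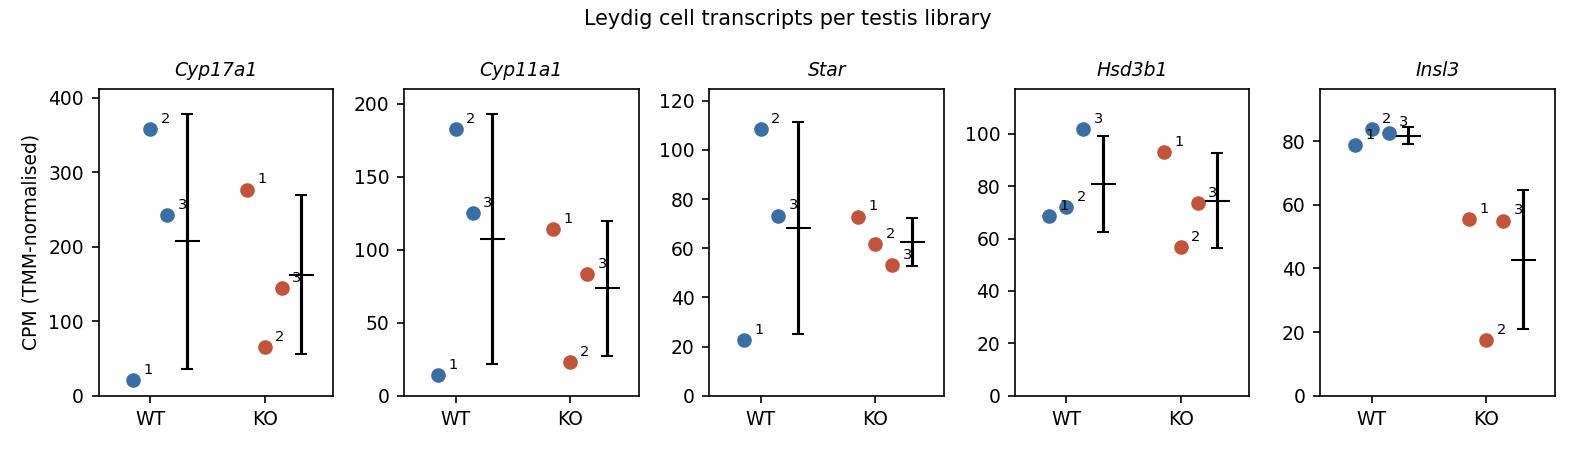
TMM-normalised CPM (y axis, linear, from 0) of Cyp17a1, Cyp11a1, Star, Hsd3b1 and Insl3 in each library (numbered points), with the mean and SD of each genotype as a bar with caps. WT 1 is the lowest library for Cyp17a1, Cyp11a1 and Star, at 21.1, 14.0 and 22.7, whereas its Insl3 level of 78.8 lies beside those of WT 2 and WT 3.

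Markers of tissue that can be carried along with testis did not pass as lists with all 6 libraries, the low-count filter used here and no block. Of 17 epididymis genes 13 had a count in at least 1 library, but only 3 passed the low-count filter and were tested. These 3 had a median log2 fold change of 0.01, a mean of -0.03 and a camera direction of up (adjusted p = 0.927). Cst8 was at 161 ± 6.09 CPM in WT and 183 ± 33.7 in KO. Whether its reads came from epididymis or from the testis itself was not tested, so its level does not measure carried-over tissue. Of 10 blood genes 3 were tested, with a median of -0.46 (camera, adjusted p = 0.108). The adjusted p was 0.0467 with a mean of at least 5 CPM and 0.00208 with the replicate number as a block. It was 0.000224 without WT 3 and 0.0210 without KO 2. The adjusted p of this list was 0.498 without WT 2 and 0.801 with an estimated correlation. Hbb-bs, an adult beta globin gene, had 9.75 ± 3.55 CPM in WT and 5.72 ± 1.89 in KO (SD, n = 3; log2 fold change -0.77). It passed adjusted over the list alone (0.0375) and not over all genes (0.965), and its reads are uncertain because globin genes have near-identical copies.

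Transcripts of cytosolic ribosomal proteins were lower in KO as a list, by a small amount. The median log2 fold change of 85 tested genes was -0.10, with 73 below 0 (camera with a preset correlation, adjusted p = 1.62e-06). With an estimated correlation the adjusted p was 0.801, and without KO 2 it was 0.0569 with a median of -0.05. In edgeR 15 members had an unadjusted p under 0.05, all lower, and 1 passed adjusted over the list alone, Rps28 (0.00161). Rps21, Rpl38 and Rps19 had log2 fold changes of -0.45, -0.47 and -0.35, each with an adjusted p of 0.159 over the list alone. Relative to the WT mean the list median was -0.20 in KO 2, -0.09 in KO 3 and -0.02 in KO 1, and it was -0.07 in WT 1. Ribosomal protein genes share sequence with many processed pseudogenes, so their single-gene values are uncertain. The 12 tested protein-coding transcripts of the mitochondrial genome had a median of -0.03 (adjusted p = 0.530), with mt-Atp6 at -0.42 and mt-Nd2 at 0.06.

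Stress, immune and lipid pathways had 0 called members and 0 members that passed adjusted over the list alone. The 16 tested p53 and apoptosis genes had a median log2 fold change of -0.04 (camera, adjusted p = 0.490), with the pro-apoptotic Bax at -0.27 and Mdm2, which restrains p53, at 0.11. The 15 immediate early and heat shock genes had a median of 0.03, a mean of -0.01 and a camera direction of down (adjusted p = 0.879), with Junb at -0.41 and Hsph1 at 0.18. The 11 interferon response genes had a median of -0.05 (adjusted p = 0.963), with Bst2 at -0.58 and Mx1 at 0.31. The 19 genes of cholesterol synthesis had a median of -0.0023 (adjusted p = 0.879), with Cyp51 at 0.27.

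Genes beside the deleted locus were compared to ask whether its loss went with changes nearby. Of 28 tested genes within 1 Mb of 1700052I22Rik 0 were called in edgeR, over all genes or adjusted over these genes alone. DESeq2 also called 0. In edgeR 4 of the 28 had an unadjusted p under 0.05, against 894 of 19320 over all genes. Besides Pcnx these were Adam4 (log2 fold change 0.36) and Gm4787 (0.32) on its side, and Zfp36l1 (-0.35) on the other. Adjusted over these genes alone, their p in edgeR was 0.132, 0.132 and 0.142. Srsf5, a splicing factor gene 21055 bases away, had 106, 103 and 97.0 CPM in WT and 104, 120 and 117 in KO (log2 fold change 0.15). Gm20337, a long non-coding gene on the side of Srsf5, lay nearer, at 18224 bases, and had a log2 fold change of 0.13. Susd6, the nearest tested gene on the other side, at 80790510 to 80880835, had a log2 fold change of 0.01. Pcnx, named after its values were seen, had the smallest p of the 28. It lies 935574 bases away, at 81860023 to 82000924, and had 88.7, 178 and 78.8 CPM in WT against 175, 203 and 188 in KO. Its log2 fold change was 0.71 (95% interval 0.26 to 1.17), with an adjusted p of 0.127 over these genes alone in edgeR. The smallest such value among the 28 was 0.0377 in limma-voom. In edgeR it was 0.0285 without KO 2, 1.40e-06 without WT 2 and 0.00167 with the replicate number as a block. With no low-count filter Pcnx was called over all genes in edgeR (adjusted p = 1.05e-12). That fit took the spread of the trend in place of the spread of Pcnx between libraries. Without WT 2 the log2 fold change of Pcnx was 1.17 and its adjusted p over all genes 0.000493. By chromosome, the call was 1 of 732 tested genes on chromosome 12 (Fisher's exact test, two-sided, adjusted p = 0.796). The called gene was the target itself, so its chromosome and class were fixed by the design. Neither this test nor the test by class below can therefore show where other changes fall. The 782 tested genes of the X chromosome had a median log2 fold change of 0.0020 and the 76 of the Y chromosome -0.07. By class, 0 of 15178 protein-coding and 1 of 2717 long non-coding genes were called (Fisher's exact test, two-sided, p = 0.141 for the long non-coding class).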

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

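Leaving out WT 1 and KO 2 together, and the gene length correction, were chosen after the results were seen. 1700052I22Rik was called under all 18 alternatives to the gene test, with adjusted p from 2.41e-08 to 2.17e-05 when 1 library was left out. The number of genes changed in KO testis stayed at 1 except with no low-count filter (50, of which 21 higher and 29 lower), DESeq2 (2), WT 1 and KO 2 left out together (9, of which 5 higher and 4 lower) and 1 library left out in turn (1 to 3). With no filter edgeR's prior degrees of freedom, median 10.4 with the filter of the reported test, became infinite, so that each gene took the spread of the trend; for the other counts the cause was not tested. Of the genes near 1700052I22Rik, the called number of 0 became 1 with no filter and ranged from 0 to 1 with 1 library left out (Pcnx without WT 2), and the smallest adjusted p over these genes alone was 0.0377 in limma-voom, 0.0399 with sample weights, 0.00167 with the block and 0.0285 without KO 2. The number of called lists, 2, became 6 with a mean of at least 5 CPM, 0 with an estimated correlation, 0 with fry (adjusted p = 0.718 for the ribosomal and the macrophage list) and 1 to 4 with 1 library left out, 4 without WT 1 and 1, the blood list, without KO 2. Of 93 named genes besides the target 85 were never called, and of 21 lists 14. Replicate numbers did not pair the samples, since deviations of libraries with the same number correlated at -0.17, -0.03 and 0.11 and share only a number; the replicate block left 1 gene and 860 unadjusted calls, called the blood list (0.00208) and ended no list call. Directions turned only for results not called with all 6 libraries. With library size alone these were Rnase10 (-7.92e-06) and the interferon list (adjusted p = 0.947); with no filter the interferon (0.392) and immediate early (0.932) lists; with a mean of at least 5 CPM the histone variants (0.835); with sample weights Tnp1 (0.041); with the block the interferon list (0.943). Without WT 1 and KO 2 they were Tnp1 (0.14), Prm1 (0.079), immediate early (0.752), histone variants (0.559) and manchette (0.889). With 1 library left out, log2 fold changes ranged over both signs for Tnp1 (-0.19 to 0.16), Tnp2 (-0.073 to 0.26), Prm1 (-0.21 to 0.056), Lcn2 (-0.54 to 0.017), Rnase10 (-0.11 to 0.11), mt-Co2 (-0.19 to 0.0054) and mt-Nd2 (-0.011 to 0.11). Lists whose direction turned in at least 1 of these fits had adjusted p, over all of these fits, of 0.337 to 0.995 (histone-to-protamine exchange), 0.669 to 0.924 (histone variants), 0.805 to 0.995 (manchette), 0.352 to 0.944 (meiotic), 5.54e-06 to 0.982 (Leydig, which turned without WT 3, at 0.924), 0.523 to 0.941 (myoid), 0.496 to 0.995 (epididymis), 0.368 to 0.924 (immediate early), 0.523 to 0.924 (interferon), 0.109 to 0.955 (cholesterol) and 0.159 to 0.843 (mitochondrial genome). Adjusted p ranged then from 1.12e-07 to 0.0569 for the ribosomal list, 2.17e-08 to 0.0652 for macrophages, 0.00300 to 0.869 for the acrosome, 0.00991 to 0.498 for Sertoli cells and 0.000224 to 0.498 for blood. The causes were not tested. Depth limits the scarcest genes. In simulations with 200 changed genes each the test found 41.5% of 1.5-fold and 70.1% of 2-fold changes, so that many changes of these sizes can be missed.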

Other observations

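The tests of KO 2 alone, of interstitial tissue, of Leydig cell number in WT 1, and the fits without WT 1 and KO 2 or with a length correction were chosen only after the results were seen. Of the 9 genes called without WT 1 and KO 2, 4 had KO 3, KO 1 and WT 1 as their 3 highest libraries. CT010467.1, annotated as ribosomal RNA, had 1062, 666 and 676 CPM in WT 1 to WT 3 and 1166, 547 and 1614 in KO 1 to KO 3. Gm23935 had 594, 313 and 330 CPM in WT and 670, 321 and 823 in KO. Lars2, the mitochondrial leucyl-tRNA synthetase gene, had 285, 126 and 126 in WT and 231, 161 and 388 in KO. Rpl30, a ribosomal protein gene, had 134, 83.4 and 82.7 in WT and 139, 64.7 and 140 in KO. With all 6 libraries and the low-count filter none of these passed in edgeR (adjusted p = 0.965 for CT010467.1, Gm23935 and Lars2 and 0.969 for Rpl30). With no filter CT010467.1 (4.89e-08), Gm23935 (4.13e-10) and Lars2 (1.46e-07) were called, each with the spread of the trend in place of its own. Gm14632, a predicted gene of the X chromosome, had 25.9 CPM in WT 3 and 0.499 and 0.836 in the other WT libraries. Gm5797 had 22.4, 13.0 and 5.12 CPM in WT and 5.85, 5.50 and 4.21 in KO, and was called without WT 3 (adjusted p = 0.0140).

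Of the 10 splits of the 6 libraries into 3 and 3, 7 gave 1 or more called genes, counting the real one, which gave 1. The highest other count was 189, for WT 1, WT 2 and KO 2 against the rest, which points to a structure of the samples that genotype does not describe. With 10 splits no share under 0.05 can be reached. Unadjusted calls ran from 293 to 2432 in the other splits, against 894 in the real one. Called lists ran from 0 to 5 in the other splits, against 2 in the real one. Of the 9 other splits, 4 called at least as many lists as the real one.

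The ribosomal protein list was lower in KO by a median log2 fold change of -0.10. Short genes might have been recovered less well in the KO libraries. Non-ribosomal genes matched on length and expression had a median of -0.0043 (95% bootstrap interval -0.011 to 0.0063, 666 genes). After a length correction the list was called with the preset correlation (camera, adjusted p = 5.55e-07). Without the correction its adjusted p was 0.801 with an estimated correlation. Both length tests used the deposited length per gene (list median 1734 bases), not the length of the expressed transcripts. They argue only against a bias along that gene length and cannot exclude one along transcript length. The 177 genes of the shortest length class, ribosomal ones included, had a median of -0.21 in KO 2, where the list stood at -0.20. Their median was 0.061 in KO 1, 0.030 in KO 3 and -0.033 in WT 1. A bias along transcript length in KO 2 stays open. KO 2 as the sole source cannot be told apart from a shared shift. Without KO 2 the median was -0.051 with a camera adjusted p of 0.0569. Without KO 2 and WT 1 the list was called with the preset correlation (camera, adjusted p = 0.00238, median -0.093). WT 1 was the lowest WT library for this list, so leaving it out by itself widens the difference. That call therefore does not argue against KO 2 as the sole source. As small a p came from 2 of the 10 splits, 7.70e-08 for the real one and 3.01e-08 for the smallest other, and 10 splits are too few for a share under 0.05. Loss of the transcript stays open as an untested explanation.

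The macrophage list was lower by a median log2 fold change of -0.31. Less interstitial tissue in the KO samples would lower endothelial and Leydig markers alike; their joint median lay 0.176 above that of the macrophage list (95% bootstrap interval 0.0026 to 0.273, 30 genes). This stays open, because the interval included 0 for endothelial markers alone (-0.00095 to 0.360) and for Leydig markers alone (-0.051 to 0.261). The Leydig difference also depended on WT 1. Without WT 1 the Leydig median lay below that of the macrophage list, at -0.42 against -0.35. The endothelial median was then -0.22. KO 2 alone also stays open. Without it the median was -0.252 (camera, adjusted p = 0.0652). Without KO 2 and WT 1 the list was called with the preset correlation (camera, adjusted p = 0.00340, median -0.23). With all 6 libraries and an estimated correlation the adjusted p was 0.801. WT 1 was the lowest WT library for this list, so the call without it does not weigh against KO 2 alone. KO 3, at -0.05 against the WT mean, lay above WT 1 at -0.15. As small a p came from 2 of the 10 splits, 5.44e-06 for the real one and 2.23e-08 for the smallest other, too few splits for a share under 0.05; a genotype effect on testis macrophages may remain and was not tested further.

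In WT 1 some steroid synthesis transcripts, among them Cyp17a1, Cyp11a1 and Star, were far below those of WT 2 and WT 3. Fewer Leydig cells in that sample would lower Insl3 alike, but Insl3 in WT 1 was 0.947 of its mean in WT 2 and WT 3 (95% counting interval 0.889 to 1.01), whereas Cyp17a1 was 0.0704 (0.0634 to 0.0780). Cyp11a1 was at 0.0913 and Lhcgr, the luteinizing hormone receptor gene, at 0.213, whereas Hsd3b1 and Srd5a1 were at 0.788 and 1.05. Of the 18 Leydig cell genes only Srd5a1 lay above 1. Nr5a1 was at 0.657, Mgst1 at 0.702, Agt at 0.717 and Scarb1 at 0.761, each with a counting interval wholly below 1. Whether somewhat fewer Leydig cells account for these smaller drops was not tested. A lower steroidogenic state of the Leydig cells in that sample is a candidate explanation. It was not tested, since the labels give no age, time or treatment that could test it.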
